A study of Mus musculus with 14 samples.

How the data were processed

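The study sequenced ribosome-protected fragments of 25 to 35 nt (Ribo-seq) and RNA fragments of 40 to 60 nt (RNA-seq) from mouse embryonic fibroblasts treated with cycloheximide at 100 µg/ml. The 14 libraries cover Scram, METTL3 knockdown and ABCF1 knockdown with 2 replicates per assay each, and Torin1 (250 nM, 2 h) with 1 library per assay. The sources used here do not say whether replicates were separate cultures, so p values measure only the spread between these libraries.

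The deposited files give RPKM, which the authors computed after trimming with cutadapt and mapping with Bowtie to GRCm38 per the submitters' processing notes; tool versions, the annotation release, the rule for reads with several positions and the read minimum are not given in the sources used here. Each file holds 1 value per Ensembl transcript. Multiplying the deposited RPKM by the GENCODE M21 length gave whole multiples of 1 step per file, within 0.02 of a read, for 98.7% to 98.8% of Ribo-seq values over coding length and 80.5% to 85.4% of RNA-seq values over whole transcript length. Length and depth are therefore divided out, and the step gives the depth, 1764404 to 5155237 reads in Ribo-seq and 1197860 to 3802703 in RNA-seq. The smallest depth sets the precision, and for genes of few reads a change of small size was not detectable. Replicate 1 files list transcripts from 1 read up, with 1.18 to 1.36 transcripts per gene. Replicate 2 and Torin files list them from about 5 reads up, with 1 transcript per gene. Each gene was represented by 1 transcript, and where that was absent from a file the gene was set to 0. In the second set this means under about 5 reads, or a gene listed there under another transcript. A fold against a 0 depends on the pseudocount and is no measured fold. In replicate 1 RNA-seq a 0 need not mean a low level. Of 1000 genes with at least 100 reads in each RNA-seq library of the second set, 22 lacked the kept transcript there, and 5 had no transcript listed. Lars2, Rpl13 and mt-Co2 were not listed there, with at least 100 reads in each RNA-seq library of the second set.

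Of 22453 transcripts, 22356 matched GENCODE M21 by identifier and 97 did not. For each of the 14241 genes 1 transcript was kept, and 5107 genes had more than 1 listed. Where a single gene is called not listed below, the kept transcript had no value. Each library was scaled to a common median over tested genes, and log2(RPKM + 1) was taken. A gene was tested if it was listed in at least 0.5 of the libraries of the fit with a mean RPKM of at least 1, which left 9018 genes in RNA-seq, 9531 in Ribo-seq and 9409 for TE.

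Group differences were fitted with limma 3.58.1 (lmFit, contrasts.fit, eBayes with trend) in R 4.3.3, with 3, 3 and 6 residual degrees of freedom for RNA-seq, Ribo-seq and TE. TE changes were interaction contrasts over both assays. Adjusted p values are Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. The spread of the lone Torin library per assay was assumed to be that of the other groups. Before the data were examined, the fit without a replicate block was chosen, with the block as an alternative, together with the gene lists, comparisons, alternatives and the rule for naming genes. For the block, whether same-numbered libraries go together was checked on deviations from their group means: replicate 1 libraries correlated at 0.82 to 0.88 in RNA-seq and 0.91 to 0.94 in Ribo-seq. Torin libraries share the listing rule of replicate 2 and took its block level.

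In simulated data with 200 genes changed by 2-fold or 4-fold, the unblocked fit recovered 0% of them. The blocked fit recovered 24.7% and 80.2% for METTL3 in RNA-seq (15 false among 116 calls), 24.5% and 92.8% in Ribo-seq (9 among 123), and 2% and 45.4% in TE (2 among 48). For Torin it recovered 5.1% and 66% in RNA-seq (20 among 87), 17.2% and 88.9% in Ribo-seq (60 among 165), and 0% and 0% in TE (2 among 2). Blocked calls therefore held more false ones than the nominal share in several cases.

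Of 30 gene lists written before the data were examined, 27 had at least 4 tested members, and 237 list by comparison tests were adjusted together. Lists were tested with camera at a preset correlation of 0.01, which gave 62 calls, and 75 with the block. With an estimated correlation 0 lists passed, with a lowest adjusted p of 0.611, and fry called 0, either with or without the block. No list call is therefore independent of the preset correlation. List medians within the second set were compared with 10000 expression-matched lists. These were drawn from all tested genes, TOP genes included, so a median inside their range does not show that a list was unchanged.

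Genes named are both targets; genes past the test that moved the same way in each replicate, 5 per direction, or else the 3 with the lowest p as values only; the 4 members with the lowest p of each list that passed; and always 2 members of 6 lists on translation and stress. A further rule, naming genes past the blocked fit, was added after the values were seen. Only part of the genes these rules choose is named, and 1 of the 5 past the blocked fit between the knockdowns is not reported here. Alternatives tried were other pseudocounts, no scaling, quantile normalization, other filters on level and listing, the block, leaving out each replicated library, TE from paired differences, and libraries not shared between comparisons. Added after seeing the data were the block with other settings, RPKM summed over transcripts and voom weights on recovered reads. Splits of the samples into other groups were not counted, since no group has 3 libraries. Correlations across genes were compared with 200 simulations of unchanged groups. Tables and figures used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9.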

Results

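Ribosome-protected fragments (Ribo-seq) and RNA fragments (RNA-seq) were sequenced from mouse embryonic fibroblasts in 14 libraries, 7 per assay. The 4 groups were a scrambled control hairpin (Scram), knockdown of METTL3, the methyltransferase that writes N6-methyladenosine on mRNA, knockdown of ABCF1, an ATP-binding protein that associates with ribosomes, and Torin1, an inhibitor of the kinase mTOR. Scram and each knockdown had 2 replicates per assay, and Torin1 (250 nM for 2 h) had 1 library per assay. The depth that the deposited RPKM values imply was 1764404 to 5155237 assigned reads for Ribo-seq and 1197860 to 3802703 for RNA-seq. Translational efficiency (TE) is the log2 Ribo-seq change minus the log2 RNA-seq change. The series title poses the question of which mRNAs are translated without the cap-binding complex eIF4F, and the knockdowns and Torin1 were each compared with Scram. Whether Torin1 was given to Scram or to untreated cells, and whether the other libraries received vehicle, is not given in the sources used here, so a Torin minus Scram value may include an effect of the hairpin or the vehicle.

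Both targets were lower in their own knockdown in each replicate. Mettl3 (ENSMUST00000022767, GRCm38 chromosome 14, 52294841 to 52305128, minus strand) had 12.3% and 38.7% of the Ribo-seq level of Scram of the same replicate in METTL3 knockdown, a log2 change of -1.91 (SE 0.45). Its RNA-seq level was 29% and 77.7% of Scram, a log2 change of -0.90 (SE 0.42), counted from 12 and 9 reads. Abcf1 (ENSMUST00000043757, chromosome 17, 35956819 to 35969761, minus strand) had 29.3% and 47.8% of the Scram RNA-seq level in ABCF1 knockdown, a log2 change of -1.37 (SE 0.36). Its Ribo-seq level was 34.3% and 50.6%, a log2 change of -1.23 (SE 0.62). In the other groups Mettl3 ranged from 62.3% to 188.8% of same-replicate Scram, and Abcf1 from 76.5% to 124.2%. In the planned fit none of these 4 target changes passed the test over all genes (limma, adjusted p = 1).

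**Figure D1:**
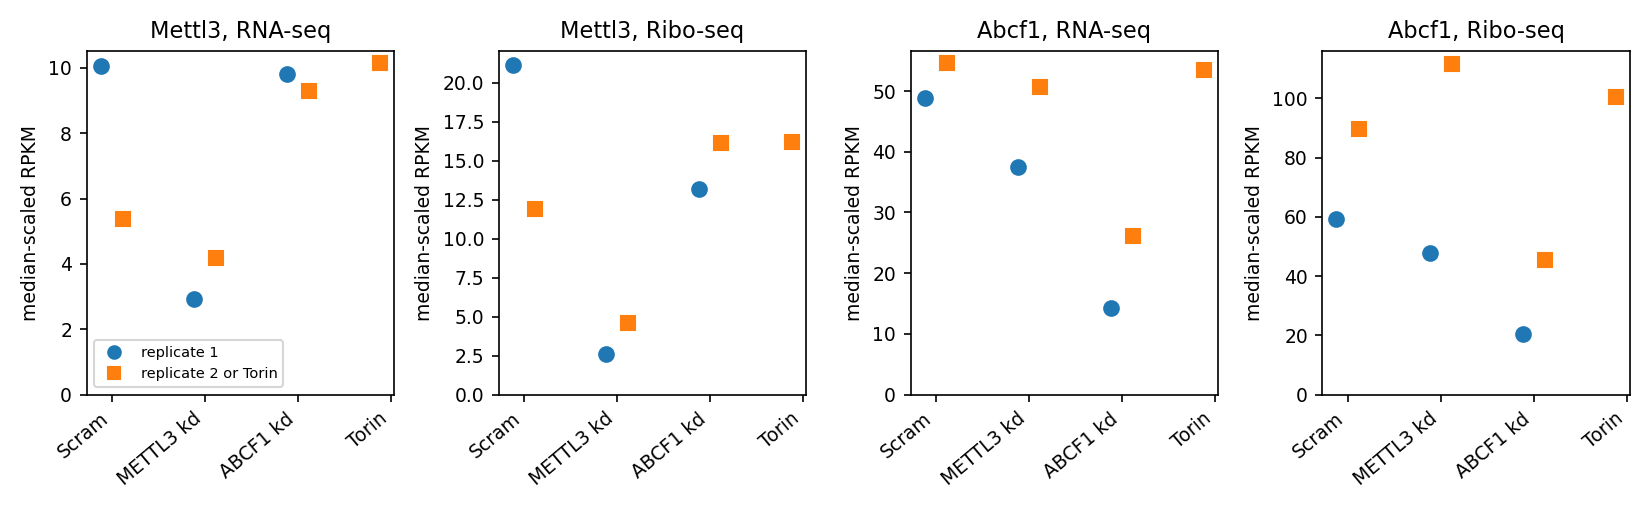
Levels of Mettl3 and Abcf1 in each library, in deposited RPKM scaled to a common median (linear axes from 0), with 1 point per library, circles for replicate 1 and squares for replicate 2 and Torin. Each target is lowest in its own knockdown within each replicate, Mettl3 at 12.3% and 38.7% of Scram in Ribo-seq and Abcf1 at 29.3% and 47.8% in RNA-seq.

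The libraries fell into 2 sets that did not follow the groups: the replicate 1 libraries, and the replicate 2 libraries with both Torin libraries. Correlation across genes was 0.86 to 0.97 within sets and 0.58 to 0.67 between them in RNA-seq, and 0.92 to 0.98 within and 0.65 to 0.71 between in Ribo-seq (genes are not independent replicates). Lars2, a mitochondrial leucyl-tRNA synthetase gene, held 35.36% to 41.61% of the RNA-seq reads of the second set, and it was not listed in the first. In Ribo-seq, counted over coding length, it held 0% to 0.002% of the reads. These RNA-seq reads are therefore not taken as a high level of its mRNA, and their origin was not tested. Tmem38b held a further 8.2% to 10.9% in the second set. The RNA-seq depths given above include these reads, so less was left there for other genes. Knockdown changes are balanced over the sets, so a term for the set (replicate block) leaves their size as it is. A Torin change against both Scram libraries holds part of the set difference, so the change within the second set (Torin minus Scram replicate 2) is given beside it for the lists.

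With Torin1 the TE of mRNAs with a 5' terminal oligopyrimidine tract (TOP mRNAs, which encode ribosomal proteins and translation factors) fell. The TE of the 70 measured ribosomal protein genes fell, with a median log2 change of -2.14 (adjusted p = 1.55e-25, or 0.611 with an estimated correlation between genes) and 69 of 70 lower within the set, where the median was -2.21 against -0.45 to -0.15 for expression-matched lists. The 23 other TOP genes fell by a median of 1.44 on the log2 scale in TE (adjusted p = 2.92e-12, or 0.611 with an estimated correlation), -1.33 within the set against -0.61 to -0.05 for matched lists, with 23 of 23 lower. Rpl11 (chromosome 4, 136049731 to 136053393) had a TE change of -3.08 (SE 0.42), with Ribo-seq levels of 413.5 and 481.11 in Scram and 53.41 with Torin against RNA-seq levels of 81.69, 81.31 and 84.5. Eef1b2, an elongation factor subunit, had -2.97 (SE 0.52) and Pabpc1, the poly(A)-binding protein, -2.47 (SE 0.55). Of the ribosomal protein genes 0 passed the TE test over all genes and 5 passed adjusted over the list alone, and of the other TOP genes 0 and 3.

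In Ribo-seq the same 2 lists fell by medians of 1.79 (adjusted p = 6.06e-15) and 1.41 (adjusted p = 1.34e-07) on the log2 scale, and adjusted p = 0.661 for each with an estimated correlation. All 69 and all 23 measured members were lower within the set, with medians of -2.13 and -1.28. Of these members 0 passed over all genes, and 9 and 2 passed adjusted over the list alone. In RNA-seq the ribosomal protein list had a median of 0.63 (adjusted p = 2.8e-05, or 0.827 with an estimated correlation), but 0.06 within the set and -0.03 with the replicate block (adjusted p = 0.91). Several ribosomal protein genes have near-identical copies, and Rps23, listed in both Scram Ribo-seq libraries, was not listed with Torin.

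Mitochondrial protein genes had smaller median changes. The TE of 71 mitochondrial ribosomal protein genes fell by a median of 0.69 on the log2 scale (adjusted p = 1.56e-06, or 0.672 with an estimated correlation), -0.34 within the set against -0.26 to 0.04 for matched lists, with 54 of 71 lower. That of 69 nuclear genes of oxidative phosphorylation fell by 0.60 (adjusted p = 2.33e-06, or 0.611 with an estimated correlation), -0.46 within the set against -0.37 to -0.09, with 57 lower. Ndufa6, a complex I subunit, had a TE change of -2.07 (SE 0.44), and Mrpl22 had -1.81 (SE 0.71). Without scaling the median TE of all genes shifted by 0.78 with Torin against both Scram libraries, and these 2 medians became 0.09 and 0.21, while both TOP lists stayed negative at -1.35 and -0.62. That shift holds part of the set difference. The median RNA-seq level of tested genes was 11.98 and 8.24 in Scram replicates 1 and 2, and 7.31 with Torin. How the medians within the set depend on scaling is not shown by these values. Quantile normalization ended the call of the oxidative phosphorylation list in TE (adjusted p = 0.309) and in Ribo-seq (adjusted p = 0.301). In Ribo-seq the 2 mitochondrial lists had medians of -0.85 (adjusted p = 8e-07, or 0.691 with an estimated correlation; -0.38 within the set) and -0.71 (adjusted p = 4.05e-05, or 0.661; -0.52 within the set).

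Among further lists, changes of Torin in proteasome, lysosome, fibroblast and histone genes depended on scaling or set. Their median TE changes were -0.39, -0.12, -0.69 and -1.37 (adjusted p = 0.0134, 0.0204, 0.0301 and 5.79e-07). With an estimated correlation the 4 adjusted p were 0.661, 0.661, 0.611 and 0.681. Within the set the proteasome and histone medians of -0.27 and -0.29 lay inside the -0.50 to -0.06 and -0.44 to -0.07 of matched lists, the lysosome median of -0.39 lay at the edge of -0.39 to 0.09, and the fibroblast median of -0.84 lay below -0.73 to 0.12. Against both Scram libraries, the first 3 turned to 0.42, 0.65 and 0.10 without scaling. Quantile normalization turned the proteasome and lysosome medians to 0.14 and 0.05 and ended the calls of the proteasome, lysosome and fibroblast lists (adjusted p = 0.638, 0.553 and 0.59). Immediate early genes, which answer growth signals within minutes, had medians of 0.58 in RNA-seq (adjusted p = 0.000491, or 0.718 with an estimated correlation) and 0.72 in Ribo-seq (adjusted p = 6.12e-05, or 0.681), and 0.18 and 0.31 within the set. Lysosome genes had a median of 0.34 in RNA-seq (adjusted p = 0.00271, or 0.661 with an estimated correlation), and 0.22 within the set with 19 of 26 higher. Against both Scram libraries without scaling it was -0.09, where the median of all genes shifted by -0.49.

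Over single genes, limma called 0 for Torin in RNA-seq, Ribo-seq and TE, with 203, 304 and 255 at an unadjusted p under 0.05. The lone Torin library per assay was assumed to vary like the other groups. With the replicate block, 10, 122 and 54 genes passed, of which 9, 112 and 30 were lower, and these included 48 ribosomal protein genes in Ribo-seq and 18 in TE. In simulated data the blocked Torin fit made 60 false calls among 165 in Ribo-seq and 20 among 87 in RNA-seq. In TE it recovered 0% of the 2-fold and 0% of the 4-fold changes, with 2 false calls among 2. Single blocked calls are therefore uncertain. With the block Klhdc8a had a Ribo-seq change of 2.75 (SE 0.32, adjusted p = 0.0143), and Eif4ebp1, which encodes an mTOR-regulated repressor of eIF4E, had -1.95 (SE 0.28, adjusted p = 0.0244). Without it they had 2.62 (SE 0.43) and -2.28 (SE 0.57), each with adjusted p = 0.89. Apold1 was listed at 32.56 with Torin and in neither Scram Ribo-seq library.

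**Figure D2:**
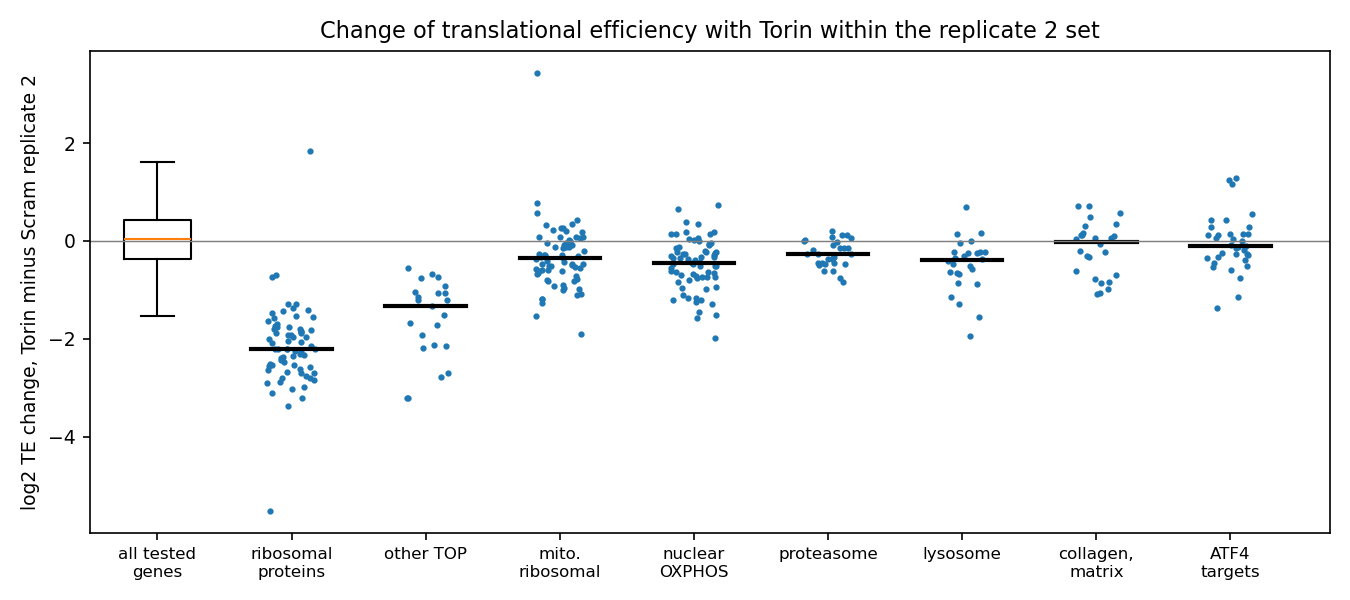
Log2 TE change of Torin against Scram replicate 2 (y axis, median-scaled values) for all tested genes (box with quartiles and median, whiskers to the last gene within 1.5 box heights, further genes not drawn) and for 8 gene lists (1 point per gene, bar at the median). The ribosomal protein and other TOP lists lie lowest, with medians of -2.21 and -1.33. Against both Scram libraries, a comparison not drawn here, the median TE of all genes shifts by 0.78 without scaling. In that comparison the mitochondrial, proteasome and lysosome lists turn positive. Unscaled values for the comparison drawn are not given.

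METTL3 knockdown was compared with Scram to ask which mRNAs change in level or translation when the methyltransferase is reduced. Contractile genes, targets of the factor SRF, fell in RNA-seq by a median of 0.24 on the log2 scale (19 genes, 13 lower and 0 higher in both replicates, adjusted p = 0.000102, or 0.661 with an estimated correlation). Acta2, smooth muscle actin, had a change of -1.42 (SE 0.30) in RNA-seq and -1.20 (SE 0.40) in Ribo-seq. Genes of inflammation under NF-kB fell by a median of 0.64 in RNA-seq (14 genes, adjusted p = 5.42e-06, or 0.661 with an estimated correlation), with medians of -0.20 and -1.06 in replicates 1 and 2. Among them Vcam1, a cell adhesion molecule, had -1.88 (SE 0.64) in RNA-seq and -2.14 (SE 0.27) in Ribo-seq, with Ribo-seq replicate differences of -1.89 and -2.39. Other members fell mainly in replicate 2 of RNA-seq: Ptgs2 had -0.32 and -4.45, Tnfaip3 0.08 and -2.11, and Icam1 -0.38 and -1.02. In ABCF1 knockdown RNA-seq Ptgs2 and Tnfaip3 did likewise, with -0.28 and -4.03, and -0.22 and -1.52. The fall of this list is therefore not particular to METTL3 knockdown.

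Hmga2, a chromatin architecture factor (chromosome 10, 120361275 to 120476469), was lower in both replicates and both assays. Its Ribo-seq level was 26.68 and 16.5 in METTL3 knockdown against 180.7 and 122.7 in Scram, a log2 change of -2.77 (SE 0.41), and its RNA-seq change was -1.26 (SE 0.56). Its Ribo-seq adjusted p was 1 without the replicate block and 0.0254 with it (SE 0.20), where it was the 1 gene called. The call was lost when METTL3 Ribo-seq replicate 2 was left out, which leaves 1 library in that group. Glycolysis and hypoxia genes fell in Ribo-seq by a median of 0.49 (20 genes, 12 lower and 0 higher in both replicates, adjusted p = 0.000593, or 0.681 with an estimated correlation). Ndrg1 had -1.34 (SE 0.40), the hexokinase Hk2 -1.13 (SE 0.59) and the glucose transporter Slc2a1 -0.95 (SE 0.33). The TE of 16 heat shock genes fell by a median of 0.31 (adjusted p = 0.0107, or 0.611 with an estimated correlation), with the co-chaperone Bag3 at -0.90 (SE 0.56).

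Collagen and matrix genes rose with METTL3 knockdown in TE, with a median of 0.43 over 26 genes (adjusted p = 0.00361, or 0.611 with an estimated correlation). Of these 17 were higher and 3 lower in both replicates, whose medians were 0.18 and 0.62. In Ribo-seq the list rose by a median of 0.40 (adjusted p = 0.00574, or 0.661 with an estimated correlation), and in RNA-seq its median was -0.03. Col5a2 had 1.21 (SE 0.30) and the crosslinking enzyme Loxl1 1.03 (SE 0.31) in Ribo-seq, and Col1a2 had 1.06 (SE 0.63) in TE. Replication histone genes rose in RNA-seq by a median of 0.21 (47 genes, 24 higher and 2 lower in both replicates, adjusted p = 7.23e-05, or 0.611 with an estimated correlation), and many histone genes have near-identical copies.

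Immediate early genes fell with METTL3 knockdown by medians of 0.68 in RNA-seq (adjusted p = 4.72e-05, or 0.681 with an estimated correlation) and 0.97 in Ribo-seq (adjusted p = 4.05e-08, or 0.661). The RNA-seq replicate medians were 0.08 and -1.45 and the Ribo-seq ones -0.32 and -1.61. Fosl1, an AP-1 subunit, had -2.99 (SE 0.65) in Ribo-seq. Sterol synthesis genes fell in RNA-seq by a median of 0.39 (adjusted p = 7.71e-05, or 0.718 with an estimated correlation), with replicate medians of 0.04 and -0.87, so both RNA-seq medians fell in replicate 2. Limma called 0 genes in RNA-seq, Ribo-seq and TE, with 63, 242 and 46 at an unadjusted p under 0.05, and 0, 1 and 0 with the block. In the planned fit no member of these lists passed over all genes tested. Adjusted over the list alone the members passing numbered 0, except for Vcam1 in Ribo-seq.

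ABCF1 knockdown was compared with Scram in the same way. Targets of ATF4, the transcription factor of the integrated stress response, fell in RNA-seq by a median of 0.51 on the log2 scale (34 genes, 25 lower and 3 higher in both replicates, adjusted p = 3.54e-07) and rose in TE by 0.49 (35 genes, 23 higher and 2 lower, adjusted p = 3.21e-07). Adjusted p = 0.611 for each with an estimated correlation. Their Ribo-seq median was 0.10 (adjusted p = 0.819). TE subtracts the RNA-seq change, so lower RNA with little change in Ribo-seq raises TE by itself. The RNA-seq and TE calls are therefore not separate findings. Slc7a5, a large neutral amino acid transporter (chromosome 8, 121881150 to 121907694), had -0.88 (SE 0.30) in RNA-seq and 1.19 (SE 0.47) in TE, Aldh18a1 had -0.68 (SE 0.26) and 0.90 (SE 0.34), and the methionyl-tRNA synthetase Mars had -0.65 (SE 0.26) and 0.94 (SE 0.35).

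Collagen and matrix genes showed the same pair of directions with ABCF1 knockdown, and here too both calls use the same RNA-seq libraries and are not separate findings. Their RNA-seq median fell by 0.39 (26 genes, adjusted p = 0.000294) and their TE median rose by 0.46 (20 higher and 0 lower in both replicates, adjusted p = 0.00114), and adjusted p = 0.611 for each with an estimated correlation. In RNA-seq fibronectin (Fn1) had -1.17 (SE 0.63), Timp3 -1.29 (SE 0.53) and Thbs1 -1.23 (SE 0.39). Contractile genes fell in RNA-seq by 0.37 (19 genes, 14 lower and 0 higher, adjusted p = 0.000425, or 0.661 with an estimated correlation), with Tagln at -1.36 (SE 0.59) and Vcl at -0.73 (SE 0.28). Initiation factor genes fell by 0.29 in RNA-seq (34 genes, 21 lower and 4 higher, adjusted p = 0.0065) and 0.25 in Ribo-seq (adjusted p = 0.00371), each with adjusted p = 0.661 with an estimated correlation. Ribosomal protein genes fell by 0.33 in RNA-seq (adjusted p = 0.0134, or 0.905 with an estimated correlation, and 0.0723 with quantile normalization), and their TE median of 0.38 passed only with the replicate block (adjusted p = 6.07e-06 against 0.161, and 0.933 with the block and an estimated correlation).

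Sterol synthesis genes fell in RNA-seq with ABCF1 knockdown by a median of 0.64 (adjusted p = 1.34e-07, or 0.681 with an estimated correlation), with replicate medians of -0.04 and -1.04. Sqle and Lss, enzymes of the pathway, had -0.95 (SE 0.27) and -0.91 (SE 0.31). Immediate early genes fell by 0.42 in RNA-seq (adjusted p = 0.00437, or 0.801 with an estimated correlation) and 0.78 in Ribo-seq (adjusted p = 1.34e-09, or 0.661), with replicate medians of 0.30 and -1.35 in RNA-seq and -0.12 and -1.50 in Ribo-seq. Both RNA-seq medians fell in replicate 2, as with METTL3 knockdown, though 13 of 23 sterol synthesis genes were lower in both replicates, among them Sqle (-0.88 and -1.02) and Lss (-0.80 and -1.01). Cyp1b1, a cytochrome P450, had -2.0 (SE 0.27) in Ribo-seq and -1.83 (SE 0.40) in RNA-seq. Limma called 0 genes in RNA-seq, Ribo-seq and TE, with 79, 107 and 37 at an unadjusted p under 0.05 and 0 with the block. In the planned fit no list member passed over all genes, and adjusted over the list alone 0 passed in these lists.

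**Figure D3:**
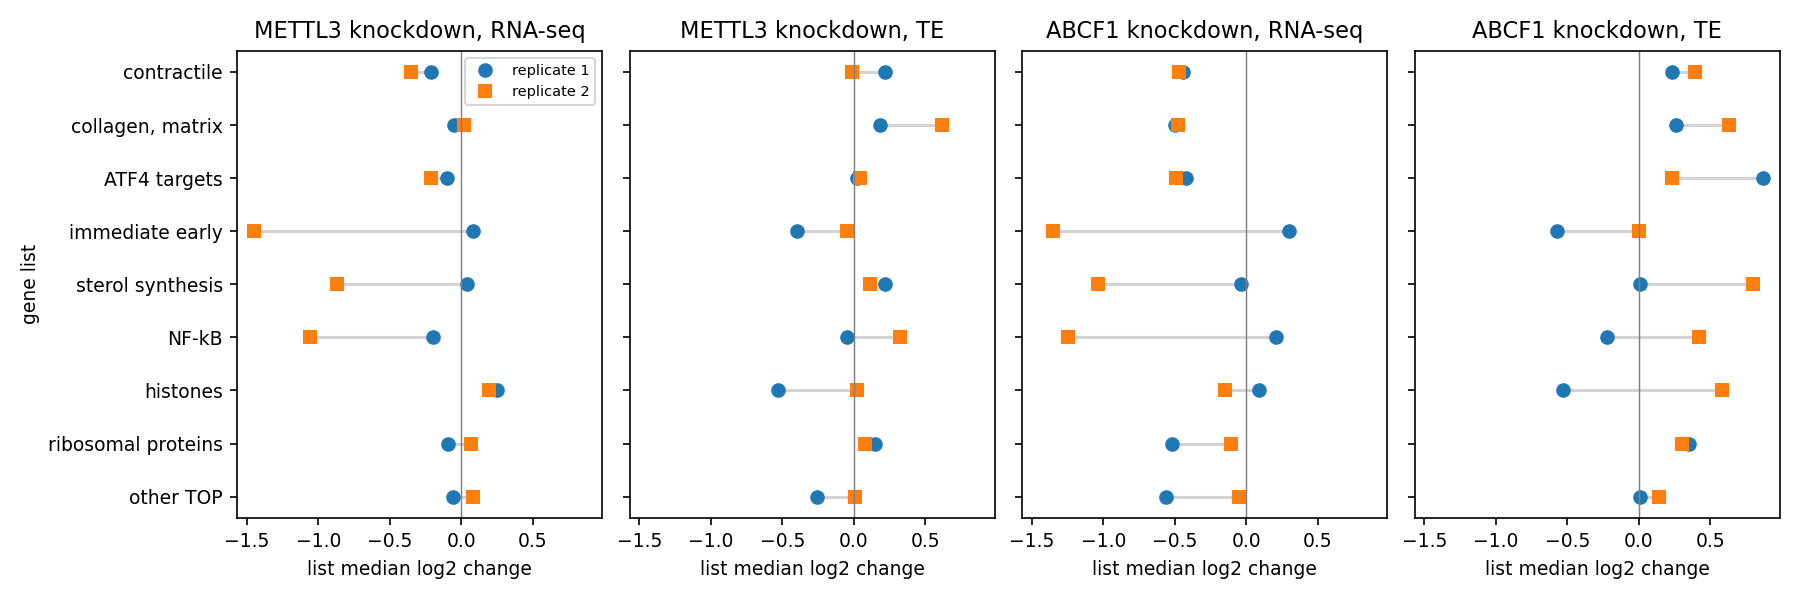
Median log2 change of 9 gene lists (y axis) in METTL3 and ABCF1 knockdown, RNA-seq and TE, each against Scram of the same replicate (x axis, median-scaled values; circles replicate 1, squares replicate 2, joined by a grey line). The ATF4 list lies at -0.42 and -0.49 in ABCF1 RNA-seq and at 0.87 and 0.23 in TE, while immediate early and sterol genes are low in replicate 2 RNA-seq and near or above 0 in replicate 1.

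The 2 knockdowns were compared with each other by the difference of their changes. Limma called 0 genes in RNA-seq, Ribo-seq and TE, with 254, 201 and 45 at an unadjusted p under 0.05, and 0, 5 and 0 with the replicate block. Across 9409 genes the TE changes of METTL3 and ABCF1 knockdown had r = 0.43, against 0.50 in simulations of unchanged groups that share the Scram libraries, and r = 0.05 and 0.08 when no library was shared. METTL3 and ABCF1 knockdown against Torin had r = 0.22 and 0.14, against 0.41 simulated for each, and 0.05 and 0.00 with no shared library. In each pair the simulated correlation was above the observed one. The covariances were 0.119, 0.115 and 0.074 for the pairs in this order, against 0.119 simulated for each. For METTL3 and ABCF1 the lower r therefore reflects a wider spread of the changes and no lower covariance. The simulations hold no set difference, while the Torin changes against both Scram libraries do, so the lower r of the 2 Torin pairs decides nothing. With the replicate block METTL3 and ABCF1 knockdown against Torin had r = 0.23 and 0.08, against 0.39 simulated for each. Their covariances were then 0.100 and 0.038, against 0.119. The r with no shared library cross the library sets and lack a comparison within the same knockdown, so they do not show that the changes differ.

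The genes with the highest and the lowest TE change with Torin were then looked at in the knockdowns. They are ranked by a median-scaled change between single libraries, so the highest genes are not shown to have kept their translation. The 1882 genes with the highest TE change with Torin (median 1.02) had a median TE change of 0.06 in METTL3 knockdown replicate 1, against 0 to 0.04 for expression-matched lists, and of 0.03 in ABCF1 knockdown replicate 1, against 0 to 0.02. The 1882 genes with the lowest (median -0.76) had medians of 0 in both. The Torin change used Scram replicate 2 and the knockdown changes Scram replicate 1, so no library was shared. With knockdown replicate 2 against Scram replicate 1, which crosses the library sets, the genes highest with Torin had 0.26 and 0.22, against 0.22 to 0.32 and 0.22 to 0.33 for matched lists, so they show no excess there, and the lowest had -0.18 and -0.09, against -0.02 to 0.05 and 0.02 to 0.11. With quantile normalization the genes highest with Torin had 0.00 in METTL3 and -0.02 in ABCF1 knockdown.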

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

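The 4 genes below were picked out because the Ribo-seq changes of the 2 knockdowns differed by a test of the difference itself, in the fit with the replicate block, which was an alternative; the planned fit gave adjusted p = 1 for each. The tests of the replicate 2 pattern and of the library sets were chosen after the result was seen, and so was the test of the shared Scram libraries, while the coding length test was written before its result was seen, with its SE over the library sets added to the reading afterwards, as was the SE over list members in the Ribo-seq test of the replicate 2 pattern.

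Angptl7, which encodes a secreted angiopoietin-like protein, was higher in METTL3 than in ABCF1 knockdown by 3.27 on the log2 scale (SE 0.23, adjusted p = 0.0254 with the block, replicate differences 3.4 and 3.14). Mmp23, a metalloproteinase gene, was higher by 3.52 (SE 0.32, adjusted p = 0.03; 3.34 and 3.7), and it was not listed in ABCF1 knockdown replicate 2. Mfap5, a microfibril protein gene, had -4.13 (SE 0.35, adjusted p = 0.03; -4.6 and -3.66) and was not listed in either METTL3 library. Cbr2, a carbonyl reductase gene, had -4.15 (SE 0.37, adjusted p = 0.03; -3.98 and -4.31), listed at 0.62 and not listed in METTL3 knockdown. For the last 3 genes the fitted size depends on the pseudocount. Leaving out either Scram library kept all 4 calls, and leaving out any 1 knockdown library left 0 of them, with the direction kept for all 4, so the calls need both replicates of each knockdown. Scram enters this comparison only through the estimate of the spread, and the genes were picked with agreeing replicates. The kept calls and directions are therefore no added support. Leaving out libraries was added after the result was seen. No technical or biological explanation was tested for these 4 genes.

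The medians of immediate early and sterol synthesis genes were lower in replicate 2 RNA-seq of both knockdowns and not in replicate 1. Their joint median was -1.04 and -1.31 in METTL3 and ABCF1 replicate 2, and 0.07 and 0.04 in replicate 1. For immediate early genes a Scram replicate 2 RNA-seq library that alone stood apart is argued against, since the separate Ribo-seq libraries show the drop too: replicate 2 minus replicate 1 had medians of -1.42 (SE 0.16) and -1.44 (SE 0.28) in METTL3 and ABCF1 knockdown, below the -0.22 and -0.24 that bound matched lists. For sterol synthesis genes this stays open, as -0.86 (SE 0.17) lay below -0.21 but -0.28 (SE 0.11) did not lie below -0.23 by its SE. These SE are over list members, which are not independent replicates, and do not measure the spread between libraries. The values of the knockdowns use the same Scram Ribo-seq libraries, so they are not independent of each other. If the Scram replicate 2 cells alone stood apart, Torin would be lower against it by a like amount, unless Torin1 was given to Scram cells that shared the deviation. The median of Torin minus Scram replicate 2 was -0.14 over both lists, 0.18 for immediate early and -0.29 for sterol synthesis genes, the last below the -0.17 to 0.13 of matched lists. These medians lie above the knockdown values, but the lists go opposite ways, Torin itself may change these genes, and which cells received Torin1 is not known. Scram cells that differed and an effect of the hairpins in that set can therefore not be told apart.

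Collagen and matrix genes had a higher TE in both knockdowns, which share the Scram libraries. In ABCF1 knockdown their RNA-seq median was also lower, which raises TE by itself, while in METTL3 knockdown it hardly changed. A trend with coding length stays open: the mean of the 4 replicate medians was 0.42 before and 0.34 after a correction on length, above the 0.2 set in advance by less than its SE of 0.17 over the 2 library sets, and METTL3 replicate 1 alone fell to 0.11. Chance values of the shared Scram libraries may still account for part. With disjoint libraries the lower median was 0.18, in METTL3 replicate 1 against an upper limit of 0.17 for matched lists, while ABCF1 replicate 1 had 0.26 against 0.28 and the replicate 2 medians of 0.62 and 0.63 exceeded 0.21 and 0.32. An effect of the knockdowns on matrix mRNAs stays open.

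The split of the libraries into 2 sets was weighed against depth and against near-identical gene copies. Depth is argued against in Ribo-seq: the METTL3 knockdown libraries had 2584477 and 2482737 reads, yet no pair across the sets correlated above 0.71. The lowest pair within a set was 0.92. In RNA-seq the METTL3 knockdown libraries, of 1577005 and 1342760 reads, correlated across genes at 0.66, below the lowest pair within a set at 0.86. That RNA-seq pair decides little. The genes Lars2 and Tmem38b held 37.59% and 10.85% of its replicate 2 reads, against 0% and 0.16% in replicate 1. Depth for the other genes was therefore unequal. A first version of the depth test counted genes absent from the first set, found 5 of 1000 and decided nothing. A different handling of near-identical copies is one candidate cause: 116 ribosomal protein and histone genes differed between the Scram Ribo-seq libraries by a median of 1.66, above the upper limit of 0.81 for matched lists. The files of the sets also differ in read minimum and in transcripts listed per gene, and whether this accounts for the split was not tested. Whether the sets also differ biologically was not tested.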

How the results depend on the processing

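The unblocked fit gave 0 gene calls for each knockdown and Torin in each assay and for the TE difference between knockdowns, and so did each setting fixed in advance except the replicate block and, for Torin TE, a pseudocount of 0.1 (25 calls, 23 higher and 2 lower). With the block the calls were 1 for METTL3 Ribo-seq and 10, 122 and 54 for Torin RNA-seq, Ribo-seq and TE. The cause was not tested, though a block removes the set difference from the spread. Leaving out any 1 library of the unblocked fit gave 0. Of the values of named genes under the alternatives, 174 passed the threshold. That 8160 others did not pass it is no sign of stability, since the unblocked fit recovered 0% of simulated changes.

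Further settings were chosen after seeing the data. The block with genes listed in every library gave 17 for METTL3 Ribo-seq, 88 for Torin Ribo-seq and 22 for Torin TE. With summed transcripts the blocked calls were 1, and 23, 158 and 83 for Torin RNA-seq, Ribo-seq and TE. With quantile normalization they were 1, and 6, 110 and 24. With voom weights they were 7 for ABCF1 RNA-seq, 94 for METTL3 Ribo-seq, 10 for ABCF1 Ribo-seq, 138 for Torin Ribo-seq (Torin Ribo calls), 1 for ABCF1 TE, 30 for Torin TE and 3 for METTL3 minus ABCF1 TE.

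Leaving out 1 library at a time in the blocked fit gave 0 for METTL3 RNA-seq, and 0 to 119 (highest without ABCF1 RNA replicate 1) for ABCF1 RNA-seq. Torin RNA-seq gave 0 to 35 (35 and 32 without ABCF1 RNA replicates 1 and 2). METTL3 Ribo-seq gave 0 to 322 (322 without Scram Ribo replicate 1, 3 without Scram replicate 2, 2 without METTL3 replicate 1, 0 without METTL3 replicate 2). ABCF1 Ribo-seq gave 0 to 122 (122 without Scram replicate 1, 2 without Scram replicate 2 or ABCF1 replicate 2). Torin Ribo calls numbered 40 to 273: 273 and 257 without Scram replicates 1 and 2, 82 and 44 without METTL3 replicates 1 and 2, 55 and 40 without ABCF1 replicates 1 and 2. METTL3 TE gave 0 to 2 (2 without METTL3 RNA replicate 1), and ABCF1 TE 0 to 90 (90 and 1 without ABCF1 RNA replicates 1 and 2, 2 without Scram RNA replicate 1). Torin TE gave 1 to 113: 1 without either Scram Ribo replicate, 17 and 16 without METTL3 Ribo replicates 1 and 2, 13 without either ABCF1 Ribo replicate, 4 and 16 without Scram RNA replicates 1 and 2, 10 and 2 without METTL3 RNA replicates 1 and 2, and 98 and 113 without ABCF1 RNA replicates 1 and 2. METTL3 minus ABCF1 TE gave 0 to 144 (144 and 1 without ABCF1 RNA replicates 1 and 2, 2 without METTL3 RNA replicate 1, 1 without METTL3 Ribo replicate 1). METTL3 minus ABCF1 Ribo-seq gave 0 to 186 (186 and 71 without Scram replicates 1 and 2, 2 and 0 without METTL3 replicates 1 and 2, 0 and 2 without ABCF1 replicates 1 and 2). The number of calls of the blocked fit therefore depends on single libraries in these comparisons, other than METTL3 RNA-seq, which had 0 throughout, and METTL3 minus ABCF1 RNA-seq was not tried.

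Of 62 list calls, 0 remained with an estimated correlation or fry, and 0 with either and the block, and why was not tested. With disjoint libraries the TE correlations were 0.05, 0.05 and 0.00, and with a pseudocount of 0.1 the ABCF1 and Torin correlation was 0.25. For the genes highest and lowest with Torin, knockdown replicate 2 against Scram replicate 1 gave 0.26 and -0.18 in METTL3 and 0.22 and -0.09 in ABCF1. For the genes highest with Torin, pseudocount 0.1 gave 0.09 and 0.05 in METTL3 and ABCF1 and pseudocount 5 gave 0.03 and 0.02. As deposited, ABCF1 had 0.06 and 0.03 in the highest and lowest genes, and with no filter on level 0.01 in the highest. With quantile normalization the highest and lowest were 0.00 and 0.00 in METTL3 and -0.02 and -0.03 in ABCF1, and with genes listed in every library 0.08 and 0.01, and 0.11 and 0.06. The cause of these shifts was not tested.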

Other observations

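Further lists passed with the preset correlation and lost the call with an estimated one, whose adjusted p follows each value. In METTL3 knockdown RNA-seq, mitochondrial ribosomal protein genes had a median of 0.09 (adjusted p = 0.0199, then 0.661; replicates 0 and 0.27), interferon-stimulated genes -0.27 (0.0226, then 0.661) and ATF4 targets -0.11 (0.0351, then 0.661). In its Ribo-seq, lysosome genes had -0.30 (adjusted p = 0.0109, then 0.661; replicates 0 and -0.58), contractile genes -0.22 (0.0223, then 0.661), heat shock genes -0.33 (0.0323, then 0.661) and NF-kB genes -0.35 (0.000496, then 0.611). In its TE, proteasome genes had -0.07 (adjusted p = 0.0301, then 0.661), glycolysis genes -0.17 (0.0316, then 0.681) and lysosome genes -0.14 (0.0316, then 0.681).

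In ABCF1 knockdown RNA-seq, the 4 ABC ATPase genes of translation had a median of -0.49 (adjusted p = 0.00242, then 0.661; Abcf1 itself passed adjusted over the list alone). That list holds the knocked-down gene Abcf1, at -1.37, so its call is partly fixed in advance. The other members had -0.68 (Abcf3), -0.30 (Abcf2) and -0.16 (Abce1), and the list without Abcf1 was not tested. In the same comparison NF-kB genes had -0.61 (0.0258, then 0.739; 0.21 and -1.25 in replicates 1 and 2), other TOP genes -0.22 (0.0323, then 0.691; -0.56 and -0.05) and the 10 mitochondrially encoded genes 0.70 (0.0205, then 0.661), where replicates 1 and 2 had 1.48 and -0.19. In its Ribo-seq, NF-kB genes had -0.47 (adjusted p = 0.0105, then 0.661; replicates 0 and -0.72) and lysosome genes -0.23 (0.0323, then 0.681; 0.01 and -0.35). In its TE, sterol synthesis genes had 0.49 (adjusted p = 0.00196, then 0.683; replicates 0.01 and 0.80), glycolysis genes -0.33 (0.00422, then 0.661), lysosome genes -0.15 (0.00422, then 0.661), mitochondrially encoded genes -0.63 (0.0338, then 0.661) and the 4 measured epithelial markers 0.86 (0.02, then 0.658). TE subtracts the RNA-seq change, whose replicate medians were -0.04 and -1.04 for sterol synthesis genes and whose median was 0.70 for mitochondrially encoded genes. For these 2 lists the TE and RNA-seq calls are therefore not separate findings. With Torin, Ribo-seq medians were -0.53 for proteasome genes (adjusted p = 0.0171, then 0.691; -0.32 within the set, inside the -0.54 to -0.13 of matched lists) and -1.16 for histones (0.0107, then 0.905, and 0.0856 with the block; -0.13 within the set, above -0.57 to -0.22), and RNA-seq medians 0.45 for histones (0.000162, then 0.611; 0.30 within the set, above -0.09 to 0.07) and 0.49 for NF-kB genes (0.0264, then 0.739; 0.06 within the set, inside -0.20 to 0.18). Quantile normalization ended the calls for mitochondrial ribosomal, interferon and, in TE, proteasome, glycolysis and lysosome genes in METTL3 knockdown. In ABCF1 knockdown it ended those for other TOP genes, lysosome genes in Ribo-seq, and epithelial and mitochondrially encoded genes in TE, and with Torin those for NF-kB genes and for proteasome and histone genes in Ribo-seq. Leaving out the scaling ended those for mitochondrial ribosomal genes, heat shock genes in Ribo-seq, and proteasome and lysosome genes in TE in METTL3 knockdown, and for NF-kB and Ribo-seq proteasome genes with Torin. In the planned fit no call was made for m6A machinery, p53 target, DNA replication, G2 and M phase, ER chaperone or muscle genes. With the block DNA replication genes passed in METTL3 knockdown RNA-seq (median 0.12, adjusted p = 0.0259) and TE (-0.13, 0.0414), each then 0.938 with the block and an estimated correlation. With quantile normalization G2 and M phase genes passed for Torin in Ribo-seq (adjusted p = 0.0316) and TE (0.0407). Endothelial, macrophage and neural markers had fewer than 4 measured members.

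Within the second set, 9 of 10 mitochondrially encoded genes had a higher TE with Torin than in Scram replicate 2, with a median of 0.57 against -0.70 to 0.08 for matched lists. Their RNA-seq was lower for 9 of 10, with a median of -0.36 against -0.14 to 0.13, while the Ribo-seq median of 0.11 lay inside -0.57 to 0.18, so the higher TE came with lower RNA. Sterol synthesis RNA was lower for 20 of 23 genes, with a median of -0.29 against -0.17 to 0.13. Against both Scram libraries neither list passed the test, and the sterol median was in the other direction, at 0.21 (adjusted p = 0.0882), and at 0.72 against Scram replicate 1 alone.

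Hypotheses on the mRNA sequence were tested next, with tests written before their results were seen, while reading them as void or undecided was settled after the values were known, for the reasons given. A 5' end of C followed by at least 4 pyrimidines in the annotated transcript was searched in genes outside the TOP lists, and the 194 of 8852 that carry it had a median TE change of 0 with Torin. The test is void, since 8 of 70 ribosomal protein genes carry the 5' end in the annotation, which is too few for it to mark TOP mRNAs. A DRACH motif, the m6A consensus, in the 5' UTR was asked of METTL3 knockdown over 9008 genes, 7044 of them with a motif. The difference in TE between genes with and without it was -0.022 and -0.01 in replicates 1 and 2, inside the -0.085 to 0.077 of reshuffled labels, a range that also holds the bound of -0.05 set in advance, so nothing is decided.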
